A study of Mus musculus with 4 samples.

How the data were processed

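Poly(A) RNA of 4 libraries of the mouse line MC38/gp100 was sequenced, 2 after DMSO and 2 after 1 µM GSK3368712, each for 5 days. Per the labels' protocols, RNA was taken with a column kit and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, the build was mm10 and the tools were HISAT2 2.1.0, SAMtools 1.2, StringTie 1.3.0 and DESeq2, without roles or settings. The program that counted reads, its strand setting and the annotation release are not given in the sources used here.

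The authors deposited a single table. It lists 51826 genes, 21948 of them protein-coding, and gives values for 12578, all protein-coding and each with at least 2 reads over the 4 libraries. A further 9370 protein-coding genes have no values. Per the file headers, 4 columns hold log2 values per library, named logCPM. The values show another scale: the mean of the antilogs over the libraries is close to the deposited base mean (median log2 difference -0.00313), and differences between libraries shrink at low counts. The slope of the group difference on the deposited fold change was 0.0106 for genes under a base mean of 10, 0.133 from 10 to 100 and 0.485 from 100 up. The deposited log2 values were therefore read as log2 normalised counts pulled toward the gene's mean, as a regularised log gives. Per the file headers, the authors' DESeq2 results fill the other columns: the base mean (a signal, the mean of counts divided by size factors), the log2 fold change with its standard error, the Wald score (fold change over its error), the p-value and the adjusted p-value. The adjusted p-value is given for 4527 genes, the lowest with a base mean of 39.8, and is empty for 8051. Columns name their group and a letter but not the labels' replicate number, so libraries are called A and B and no number was assigned.

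Whole reads were recovered from the deposited base means. The 10 lowest base means are the ways of placing 2 reads in 4 libraries and gave the authors' size factors: 1.11 for DMSO A, 0.958 for DMSO B, 0.972 for inhibitor A and 0.999 for inhibitor B. These were refined on genes with a single solution. For each gene, whole reads that give its base mean to the printed precision (15 significant digits) were searched in a window around the reads implied by the deposited fold change and, at higher base means, the deposited log2 values. A single solution was found for 12576 genes, all but Gm20721 and Tlcd1, and a solution outside the window would be missed. In 1471 simulated genes 100% came back exactly. That simulation was given its own size factors, and its windows were centred on values worked out from the true reads. It therefore did not test the estimate of the size factors or windows set from the deposited values. The recovered totals, with the 2 unsolved genes estimated, range from 1080403 to 1174891 reads per library, so a gene at the median holds about 22.6 reads and has a wide counting error. Between the 2 libraries of a group, the chi-square per gene (genes with at least 20 reads) was 2.21 over 8712 genes in DMSO and 1.47 over 8552 genes in the inhibitor group, so no pair was treated as a repeat deposit.

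The design fixed before the data were examined asked for a count model if the table held counts and for limma with a trend if it held normalised values. As the table holds no counts per library, limma 3.58.1 in R 4.3.3 was fitted to the deposited log2 values with group as the only term, over 8562 genes with a base mean of at least 10. The design named no such minimum for normalised values. It was chosen after the table, with the authors' own calls, had been opened and before limma was run, and the calls depend on it (12 higher and 4 lower without it). Benjamini-Hochberg adjusted p under 0.05 made a call, and all tests are two-sided. The variances of the deposited values differed little between genes around their trend. Limma's prior therefore had 182 degrees of freedom against 2 residual ones, so calls rest largely on the spread common to all genes. The deposited log2 differences understate changes, so log2 fold changes and standard errors in the text come from limma on log2 of recovered normalised reads plus a pseudocount of 1 (8560 genes), a scale that still understates changes of low genes. Means ± SD are of normalised reads, n = 2, and adjusted p-values are those of the fit to the deposited values, unless another source is named.

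The gene lists, 31 in all, were fixed before the data were examined. The 25 with at least 5 tested genes were tested with camera (limma; preset correlation among genes 0.01, trended variance), adjusted over the 25. Genes named are, by a rule fixed at the same time, every PRMT of the lists; the 10 largest rises and 10 largest falls among called genes that separate the groups and have a mean of at least 100 reads, leaving out predicted genes, clones and pseudogenes; for each list up to 4 called members with the smallest p, 2 per direction where both exist; genes fixed by name, among them Cd274, B2m, H2-K1, H2-D1 and Cxcl10; and Pmel. The largest changes were ranked on the deposited scale. List members given as not passing, members called only over their list, neighbours on the other strand and the genes of the closing section were chosen after their values were seen.

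On 8560 genes simulated for inhibitor against DMSO (2 libraries each, recovered means and size factors, dispersion 0.00388), limma called 98% of 100 genes changed 2-fold and 56% of 100 changed 1.5-fold, at base means of at least 50, with 2 unchanged genes called. The simulation used log2 of reads plus 1 and a single dispersion. Its chi-square per gene was 1.55 for the DMSO pair and 1.44 for the inhibitor pair, so its spread is below that of the real DMSO libraries and these shares are optimistic. Camera gave p under 0.05 to 1% of 200 unchanged sets. Genes were simulated independently of each other, so that share cannot show how camera behaves on lists of correlated genes. Gene positions and overlaps come from GENCODE release M21 on the same build. Of the table's identifiers 51633 matched it, version aside, among them 12570 with values. Exons of all transcripts of a gene were merged, and an overlap of at least 1 bp with an exon of a gene on the other strand (bedtools 2.31.1) counted. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps.

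Alternatives were no abundance filter, a mean CPM of at least 1, adjusted p under 0.01, a tested fold of 1.5, each library left out, the authors' deposited table, and for lists an estimated correlation, ranks and fry. Added after the data were seen were the column letter as a block, recovered reads with a pseudocount of 1 or 0.1 or with voom weights under 3 scalings, and tests restricted to genes with no opposite-strand exon.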

Results

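Messenger RNA was profiled in MC38/gp100 cells, a mouse tumour line. MC38 is a colon adenocarcinoma line of C57BL/6 mice, and gp100 is the melanocyte antigen encoded by Pmel. Cells were kept for 5 days in DMSO, the solvent control, or in 1 µM GSK3368712, an inhibitor of type I protein arginine methyltransferases (PRMTs), the enzymes that place asymmetric dimethylarginine on proteins. Each group had 2 libraries, called A and B after the columns of the deposited table. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the spread between them may be technical. The p-values of limma rest largely on the spread common to all genes (prior of 182 degrees of freedom against 2 residual ones). They rest little on the spread of each gene's own libraries. The table gave values for 12578 protein-coding genes. Reads counted at these genes, worked back from the deposited base means, came to 1174891 in DMSO A, 1080403 in DMSO B, 1084314 in inhibitor A and 1119384 in inhibitor B. These counts are low, with a median base mean of 22.6 reads per gene. They are reads counted at these genes and do not give the depth of sequencing.

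The most abundant values lay at genes that overlap another gene on the opposite strand. Of the 20 genes with the highest base means, 18 had an exon overlapping an exon of the other strand. They were led by Gm20721 (base mean 34785) opposite Gnas, Tlcd1 (26726) opposite Rpl23a, Phykpl (16504) opposite Hnrnpab and Snx22 (6816) opposite Ppib. Among all genes with values, 4219 (33.5%) had such an overlap and held 59.4% of the base-mean total. In the mitochondrial genome, mt-Nd6, the only protein gene annotated on its strand, was given 2881, 2592, 2033 and 1709 reads in DMSO A, DMSO B, inhibitor A and inhibitor B. The cytochrome oxidase gene mt-Co1 (opposite mt-Ts1) was given 247, 158, 194 and 192. The plus-strand gene mt-Nd5, which shares 14 bp with mt-Nd6, was given 1539, 1476, 1900 and 1673. The strand setting of the authors' counting is not given in the sources used here. A value at a gene with an opposite-strand neighbour is therefore uncertain as to which of the 2 genes the reads came from, and the neighbour is named beside such genes. Reads may have been counted on the strand opposite to the transcript, a candidate taken up in the closing section. Values at genes without such a neighbour could then be a leftover fraction and are uncertain too.

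**Figure D1:**
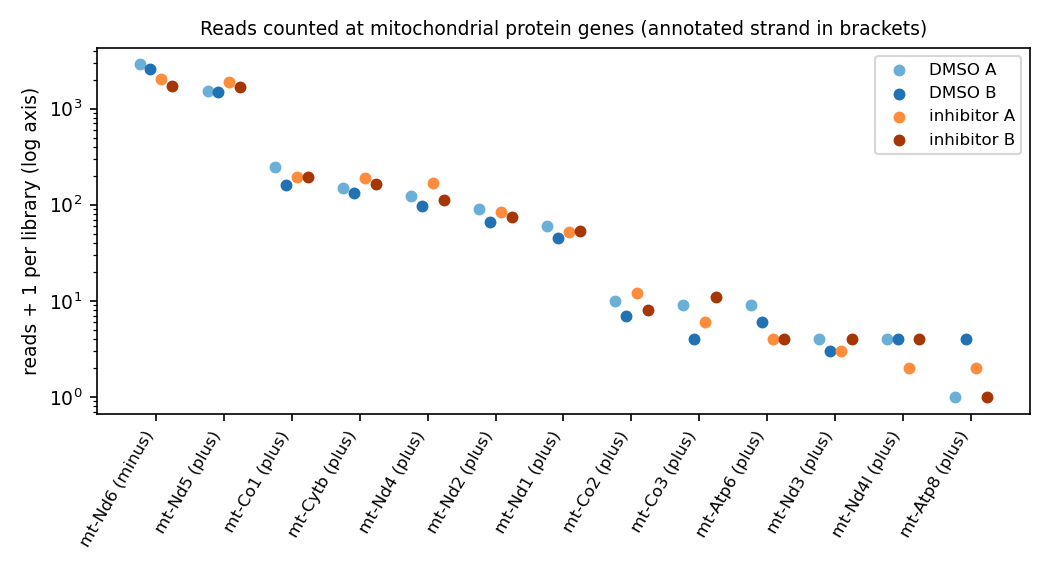
Reads per library plus 1 (log axis) at the 13 mitochondrial protein genes, one point per library, with the annotated strand in brackets. The 4 libraries gave mt-Nd6 between 1709 and 2881 reads and mt-Co1 between 158 and 247.

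The comparison of inhibitor with DMSO asks which transcripts change over 5 days of type I PRMT inhibition. Transcripts counted at some interferon-inducible genes (Gbp2, Gbp7, Cxcl10), at the collagen genes Col3a1 and Col5a3 and at some oxidative stress genes (Pgd, Srxn1, Txnrd1) rose. Those of Tuba1c, an alpha-tubulin, Vegfa, the angiogenic growth factor, and Thbs1, the matrix protein thrombospondin, fell. In the authors' deposited table Gbp7, Cxcl10, Pgd, Srxn1 and Txnrd1 did not pass (DESeq2, adjusted p from 0.097 to 0.44), while the other genes just named did. Rises at Fam69a, Tbc1d8 and Sync were larger on the log2 scale of recovered reads, but these genes have an opposite-strand exon. In all, 111 genes were higher and 72 lower with the inhibitor out of 8562 tested (limma on the deposited log2 values, adjusted p under 0.05). The median fold of normalised reads was 1.73 for the genes that rose and 0.587 for those that fell. In 182 of the 183 called genes both inhibitor libraries lay on the same side of both DMSO libraries. The exception, named here after its values were seen, was Afg3l1, which rested on DMSO A alone. Such a separation held for 41.2% of tested genes, against 33.3% by chance for 2 against 2. Calling on a group difference favours such genes, so the 182 are not separate support. The calls depend on the abundance minimum, a base mean of 10: with no minimum (12578 genes tested) 12 genes were higher and 4 lower, and 27 of the 38 called genes named below by rule were not called. Without inhibitor A the counts were 42 higher and 21 lower, and without inhibitor B 49 and 24. Without DMSO A they were 68 and 76, without DMSO B 178 and 55, and the authors' deposited table gave 16 higher and 10 lower among 4527 genes with an adjusted p, each of these 26 also called here.

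**Figure D2:**
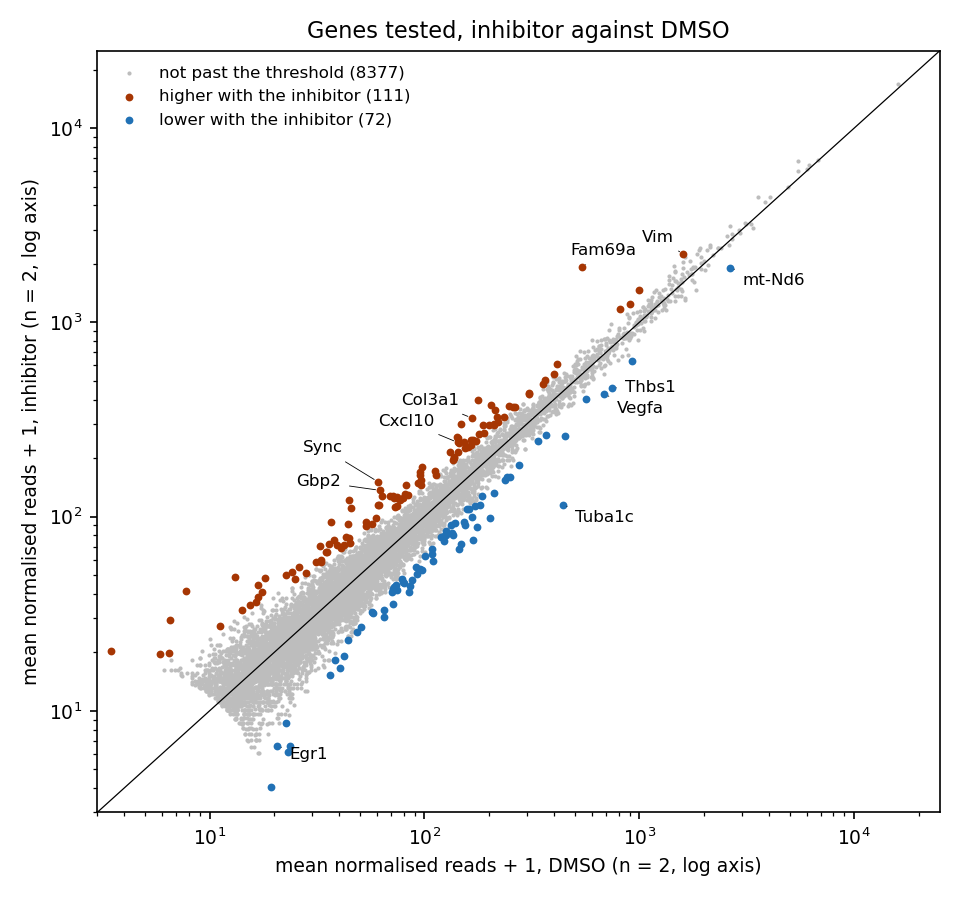
Mean normalised reads plus 1 per gene in DMSO (x axis) and inhibitor (y axis), both log axes, each the mean of 2 libraries, with the line of equality. The 111 genes higher with the inhibitor are red and the 72 lower are blue. Fam69a lies farthest above the line among genes with over 100 reads and Tuba1c farthest below.

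Among genes with a mean of at least 100 reads, the largest rise was that of Fam69a, a kinase-like protein of the endoplasmic reticulum (ENSMUSG00000029270.10, mm10 chromosome 5, 107908053 to 107987085, minus strand). Its normalised reads went from 543 ± 86.0 in DMSO to 1921.5 ± 16.5 with the inhibitor (SD, n = 2 each), a log2 fold change of 1.83 ± 0.13 (SE; limma, adjusted p = 2.2e-26). Exons of Fam69a share 953 bp with exons of Rpl5 on the other strand, and reads counted at Rpl5 had a log2 fold change of -0.20 ± 0.13. That value does not decide which of the 2 genes the reads at Fam69a came from. Tbc1d8 rose by 1.18 ± 0.14 on the log2 scale (limma, adjusted p = 2.5e-11), and its exons share 420 bp with Rpl31. Sync (opposite Rbbp4) rose by 1.32 ± 0.18 and Tex9 (opposite Mns1) by 1.08 ± 0.15. Nemf (opposite Klhdc2) rose by 0.88 ± 0.14, Klhdc9 (opposite Pfdn2) by 0.73 ± 0.14 and Fam166a (opposite Tubb4b) by 0.57 ± 0.13. Pdgfa, a platelet-derived growth factor chain that lies opposite 6330403L08Rik, rose by 0.82 ± 0.15. No opposite-strand exon was annotated at the collagen genes Col3a1 (0.96 ± 0.14; limma, adjusted p = 1.5e-07) and Col5a3 (0.87 ± 0.15; limma, adjusted p = 5.9e-06). Without inhibitor B, the call at Klhdc9 was lost (limma, adjusted p = 0.080). Fam166a lost its call without either inhibitor library (limma, adjusted p = 0.30 without A, 0.39 without B), and in the authors' deposited table Tex9 had an adjusted p of 0.40.

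At a mean of at least 100 reads, the largest fall was that of Tuba1c (ENSMUSG00000043091.8, chromosome 15, 99029891 to 99038110, plus strand), from 439 ± 13.1 to 114 ± 6.45 normalised reads. Its log2 fold change was -1.94 ± 0.14 (limma, adjusted p = 1.9e-26), and no opposite-strand exon is annotated there. Alpha-tubulin genes are close copies of each other, so reads may be shared among them and the value is uncertain. Vegfa (chromosome 17, 46016993 to 46032369, minus strand) fell from 687 ± 8.50 to 424 ± 10.6 reads, a log2 fold change of -0.69 ± 0.13 (limma, adjusted p = 0.00012). Glrp1 had a log2 fold change of -1.16 ± 0.17, Pgam2, the muscle phosphoglycerate mutase, -1.08 ± 0.18, and Zfp867, a zinc finger gene, -1.03 ± 0.17. Mrm1, a mitochondrial ribosomal RNA methyltransferase, had -0.97 ± 0.16. These 4 genes lack an annotated opposite-strand exon. Falls at genes with one were those of Tssk6 (opposite Ndufa13 and Yjefn3; -1.04 ± 0.16), Prdx5, a peroxiredoxin (opposite Trmt112; -0.77 ± 0.14), Thbs1 (opposite Gm29233; -0.70 ± 0.13) and Kif3c, a kinesin (opposite 1110002L01Rik and Gm48512; -0.54 ± 0.13). Without inhibitor A or B, Vegfa missed the threshold (limma, adjusted p = 0.11 and 0.055), as did Thbs1 without B (0.21). Kif3c passed only with all 4 libraries or without DMSO A, and in the authors' deposited table its adjusted p was 0.061.

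**Figure D3:**
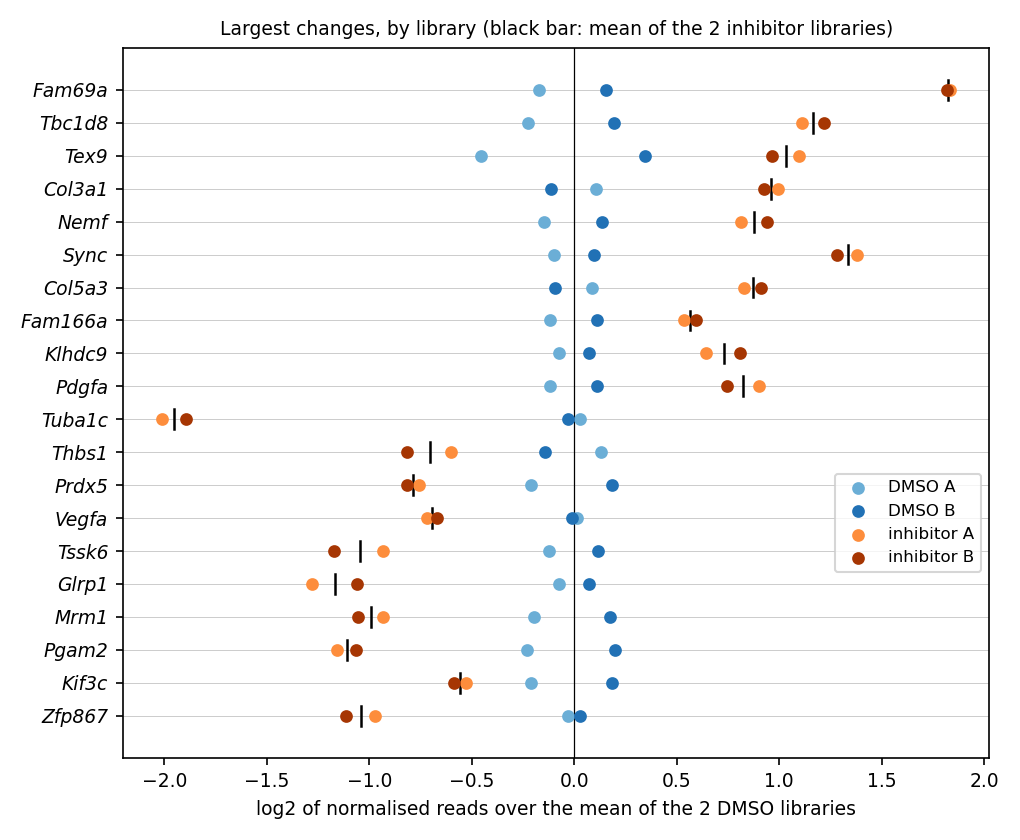
Log2 of normalised reads over the mean of the 2 DMSO libraries (x axis) for the 10 largest rises and 10 largest falls, one point per library, with a black bar at the mean of the inhibitor libraries. All 20 genes have both inhibitor libraries outside the range of the DMSO libraries, as the rule for choosing them required, and the DMSO libraries lie farthest apart at Tex9.

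Interferon-gamma-inducible genes were higher as a group: 3 of 11 tested members rose, none fell, and 8 did not pass. All 11 had a positive log2 fold change, with a median of 0.65 (camera, adjusted p = 6.7e-10, 25 lists tested). The list holds 22 genes, 17 of them with values, and the directions of most members under the abundance minimum are not given here. One of these, Cd274 (opposite AC119228.1), had a lower mean with the inhibitor (7.57 ± 4.88 normalised reads) than in DMSO (10.5 ± 1.60). With no abundance filter 17 members were tested (camera, adjusted p = 1.2e-06). With an estimated correlation among genes, adjusted p = 0.45 for this list, and likewise for the other 4 lists called. Adjusted over the list alone, 7 members were higher. Gbp2, a guanylate-binding GTPase of cell-autonomous immunity (opposite the microRNA gene Mir6381), went from 60.9 ± 6.45 to 136 ± 3.30 normalised reads, a log2 fold change of 1.14 ± 0.18 (limma, adjusted p = 6.0e-07). Gbp7 rose by 0.99 ± 0.22 on the log2 scale (limma, adjusted p = 0.0018). Cxcl10, a chemokine that attracts T cells (opposite Art3), rose by 0.76 ± 0.15 (limma, adjusted p = 0.00018). Irf1, a transcription factor of this response (opposite Gm17334), had a log2 fold change of 0.45 ± 0.16 and did not pass (limma, adjusted p = 0.12). Without inhibitor B, Gbp7 (limma, adjusted p = 0.079) and Cxcl10 (0.077) were no longer called. In the authors' deposited table Cxcl10 had an adjusted p of 0.097 and Gbp7 of 0.36.

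Genes of MHC class I antigen presentation were also higher as a group (median log2 fold change 0.24; camera, adjusted p = 0.00013; adjusted p = 0.45 with an estimated correlation). Of 19 tested members 1 rose, and 3 were higher adjusted over the list alone. Tapbp, the tapasin chaperone that loads peptide onto class I molecules (opposite Gm19412), rose by 0.47 ± 0.14 (limma, adjusted p = 0.035). It missed the threshold without DMSO B (limma, adjusted p = 0.13), inhibitor A (0.30) or inhibitor B (0.47), and with scaling by library size only (voom, adjusted p = 0.074). In the authors' deposited table its adjusted p was 0.37. The class I heavy chain genes H2-K1 (log2 fold change 0.21 ± 0.13; limma, adjusted p = 0.56) and H2-D1 (0.19 ± 0.13; 0.62) did not pass, nor did the light chain gene B2m (0.06 ± 0.13; 0.93). H2-K1 and H2-D1 are similar in sequence, so their values are uncertain. None of 33 tested interferon-stimulated genes passed by itself, and 25 had a positive log2 fold change, with a median of 0.17 (camera, adjusted p = 0.017; adjusted p = 0.45 with an estimated correlation). Adjusted over the list alone, again 0 passed. This list was not called without DMSO B (camera, adjusted p = 0.26) or inhibitor B (0.14). The checkpoint ligand gene Cd274 (opposite AC119228.1) had 10.5 ± 1.60 and 7.57 ± 4.88 normalised reads and lay under the abundance minimum for testing.

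Other immune lists were not called. In the NF-kB and TNF response list (camera, adjusted p = 0.14) 1 of 21 tested members rose, both over all genes and adjusted over the list alone: the chemokine gene Cxcl1, by 0.50 ± 0.15 on the log2 scale (limma, adjusted p = 0.035). Death receptor and T cell killing genes (camera, adjusted p = 0.82) held 1 member of 23 that fell on either adjustment, Casp8, the initiator caspase of death receptors, with 37.5 ± 6.05 and 17.2 ± 1.11 normalised reads (log2 fold change -1.07 ± 0.31; limma, adjusted p = 0.036). Immune checkpoint and T cell recognition genes (camera, adjusted p = 0.95) had no member of 6 past the threshold, and 1 was lower adjusted over the list alone, Pvr (-0.63 ± 0.20; limma, adjusted p = 0.080 over all genes). For this last list the median (0.08) and mean (0.02) were positive although the test pointed down. Cxcl1 and Casp8 were called with all 4 libraries and without DMSO A, and not without any other library (limma, adjusted p from 0.16 to 0.40 and from 0.20 to 0.28). In the authors' deposited table Cxcl1 had an adjusted p of 0.57 and Casp8 had none.

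NRF2 targets, genes of the antioxidant response, were higher as a group (median log2 fold change 0.27; camera, adjusted p = 2.1e-05; adjusted p = 0.45 with an estimated correlation). Of 18 tested members 3 rose and none fell, and 5 were higher adjusted over the list alone. Srxn1, which restores oxidised peroxiredoxins, rose by 0.68 ± 0.16 (limma, adjusted p = 0.0053). Pgd, an enzyme of the pentose phosphate pathway, rose by 0.66 ± 0.15 (limma, adjusted p = 0.0018), and Txnrd1, thioredoxin reductase, by 0.45 ± 0.13 (limma, adjusted p = 0.045). Hmox1 (0.51 ± 0.17; limma, adjusted p = 0.096) and the light ferritin gene Ftl1, which lies opposite Gm10252 (0.42 ± 0.13; 0.063), did not pass. Without inhibitor B none of the 3 was called (limma, adjusted p = 0.18 for Srxn1, 0.13 for Pgd and 0.38 for Txnrd1). Txnrd1 was not called without inhibitor A or DMSO B either, nor Srxn1 without inhibitor A, and in the authors' deposited table the adjusted p was 0.19 for Pgd, 0.38 for Srxn1 and 0.44 for Txnrd1.

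Mesenchymal marker and extracellular matrix genes were higher as a group (median log2 fold change 0.22; camera, adjusted p = 0.0063; adjusted p = 0.45 with an estimated correlation). Of 23 tested members 3 rose and 1 fell. Adjusted over the list alone, 8 were higher and 1 lower. Those that rose were Col3a1, Col6a1 (0.67 ± 0.14; limma, adjusted p = 0.00094) and Vim, which encodes the intermediate filament vimentin and falls outside the rule for named genes (0.49 ± 0.14; limma, adjusted p = 0.032). The gene that fell was Thbs1. Vim held 1597.5 ± 36.0 normalised reads in DMSO and 2244.5 ± 93.7 with the inhibitor. The type I collagen genes Col1a1 (0.43 ± 0.13; limma, adjusted p = 0.057) and Col1a2 (0.44 ± 0.14; 0.056) did not pass. This list was not called without DMSO B (camera, adjusted p = 0.058), without inhibitor A (0.14) or on ranks (0.069), and Col6a1 not without DMSO B (limma, adjusted p = 0.053) or inhibitor B (0.10). In the authors' deposited table Col6a1 had an adjusted p of 0.17.

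Few of the cell type markers on the lists reached the abundance minimum. If reads were counted on the strand opposite to the transcript, a low value does not show that a transcript was rare. Of 10 fibroblast markers 5 were tested and 1 rose, Col3a1, which the matrix list also holds (camera, adjusted p = 0.16). Adjusted over the list alone, 1 was higher and 1 lower, Pdgfra (log2 fold change -0.53 ± 0.21, opposite Gm42802 and Gm42803; limma, adjusted p = 0.23 over all genes). In the remaining marker lists fewer than 5 members reached the abundance minimum, so the lists were not tested. Of 5 leukocyte markers with values, 2 reached it: Csf1r (opposite Hmgxb3) had a log2 fold change of 0.15 ± 0.13 and Cd14 of -0.10 ± 0.35. Of 12 epithelial markers with values, 3 reached it: Krt8 (opposite Gm36026; -0.03 ± 0.34), Esrp2 (opposite Nfatc3 and 1810019D21Rik; 0.07 ± 0.14) and Ovol1 (opposite Gm31166 and AC126029.1; -0.52 ± 0.42). Of 2 melanocyte markers with values, Pmel alone reached it. Pmel, the gene behind the line's gp100 name (opposite Dgka and Cdk2), had 29.3 ± 5.86 normalised reads in DMSO and 31.4 ± 5.14 with the inhibitor (log2 fold change 0.10 ± 0.28; limma, adjusted p = 0.94). None of these genes passed, also adjusted over each list alone, and no endothelial marker reached the abundance minimum.

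In the cholesterol synthesis list 2 of 17 tested members rose, on either adjustment (camera, adjusted p = 0.094). Sqle, squalene epoxidase, rose from 94.1 ± 8.69 to 168 ± 5.41 normalised reads, a log2 fold change of 0.84 ± 0.16 (limma, adjusted p = 0.00015). Fdft1, squalene synthase (opposite Ctsb), rose by 0.47 ± 0.14 (limma, adjusted p = 0.040), a call lost without DMSO A, inhibitor A or inhibitor B (limma, adjusted p from 0.27 to 0.43). Glycolysis and hypoxia genes were not called (camera, adjusted p = 0.95), with Vegfa the 1 member of 21 that fell, on either adjustment. In the integrated stress response list (camera, adjusted p = 0.82) Chac1, a glutathione-degrading enzyme, rose by 0.76 ± 0.18 (limma, adjusted p = 0.0034) as the 1 called member of 20. Adjusted over the list alone, 1 was higher and 1 lower, Ppp1r15a, opposite Tulp2 (-0.56 ± 0.17; limma, adjusted p = 0.051 over all genes). The small heat shock gene Cryab (opposite Hspb2) fell, with -0.54 ± 0.16 (limma, adjusted p = 0.036), alone among 14 cytosolic heat shock genes, on either adjustment (camera, adjusted p = 0.95). No member of 19 in the unfolded protein response list passed on either adjustment (camera, adjusted p = 0.77). Chac1 was not called without DMSO B (limma, adjusted p = 0.064) or inhibitor B (0.36), and Cryab not without any library but DMSO A (0.091 to 0.56). In the authors' deposited table the adjusted p was 0.0999 for Sqle, 0.52 for Fdft1, 0.40 for Chac1 and 0.77 for Cryab.

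Cell cycle lists were not called. Aurka, a mitotic kinase, rose by 0.86 ± 0.24 on the log2 scale (limma, adjusted p = 0.025) as the 1 member of 33 in the G2 and M phase list, on either adjustment (camera, adjusted p = 0.094). It was called with all 4 libraries and without DMSO B (without the others, limma, adjusted p from 0.11 to 0.30), and its adjusted p in the authors' deposited table was 0.77. None of 31 S phase genes (camera, adjusted p = 0.86), 22 homologous recombination and Fanconi anaemia genes (0.14) or 30 ribosome biogenesis genes (0.14) passed, nor any adjusted over its list alone. The ribosome biogenesis list was called lower without DMSO B (camera, adjusted p = 0.049). Of 18 p53 targets none passed and 1 was higher adjusted over the list alone, Sulf2, opposite Ncoa3 (0.72 ± 0.22; limma, adjusted p = 0.064 over all genes; camera, adjusted p = 0.14 for the list). Egr1, an immediate early transcription factor, fell from 19.6 ± 2.68 to 5.58 ± 0.61 normalised reads (log2 fold change -1.65 ± 0.47; limma, adjusted p = 0.029) as the 1 called member of 17 MAPK feedback and immediate early genes, on either adjustment (camera, adjusted p = 0.26). It was called with all 4 libraries and without DMSO B, and has no adjusted p in the authors' deposited table. None of 9 Wnt targets passed on either adjustment (camera, adjusted p = 0.82).

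RNA-binding proteins and splicing factors, many of them methylated by type I PRMTs, were not called as a group (camera, adjusted p = 0.95), while fry's test for change in either direction gave an adjusted p of 0.038. Of 50 tested members 1 rose on either adjustment, Hnrnpa1, a heterogeneous nuclear ribonucleoprotein, from 245 ± 11.9 to 371 ± 8.72 normalised reads (log2 fold change 0.60 ± 0.14; limma, adjusted p = 0.0027). Hnrnpa1 has processed pseudogenes, so its value is uncertain, and its call was lost without inhibitor A (limma, adjusted p = 0.12) or B (0.18) and in the authors' deposited table (adjusted p 0.097). None of 28 cytosolic ribosomal protein genes passed on either adjustment (camera, adjusted p = 0.77), nor any of the 4 replication-dependent histone genes tested, of 11 with values. Of 7 tested mitochondrially encoded genes 1 fell, mt-Nd6, with -0.48 ± 0.14 (limma, adjusted p = 0.040), which shares 14 bp with mt-Nd5 on the other strand. Without inhibitor A or B it was not called (limma, adjusted p = 0.41 and 0.82). Adjusted over the list alone, 3 were higher and 1 lower (camera, adjusted p = 0.37).

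No PRMT gene passed. Prmt1, the main type I enzyme, had 124 ± 14.7 normalised reads in DMSO and 140 ± 9.53 with the inhibitor (log2 fold change 0.18 ± 0.16; limma, adjusted p = 0.75). The other type I genes were Carm1, opposite Yipf2 (0.12 ± 0.14), Prmt2 (0.17 ± 0.34), Prmt3, opposite Gm26856 (-0.08 ± 0.27) and Prmt6, opposite C130013H08Rik (-0.26 ± 0.23), with a camera adjusted p = 0.86 for the 5. Prmt8 is not analysed here. Prmt5 had a log2 fold change of 0.26 ± 0.21, Prmt7, opposite Smpd3 and Gm26786, of -0.04 ± 0.19, and Prmt9 of -0.01 ± 0.45. None passed adjusted over its list alone.

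**Figure D4:**
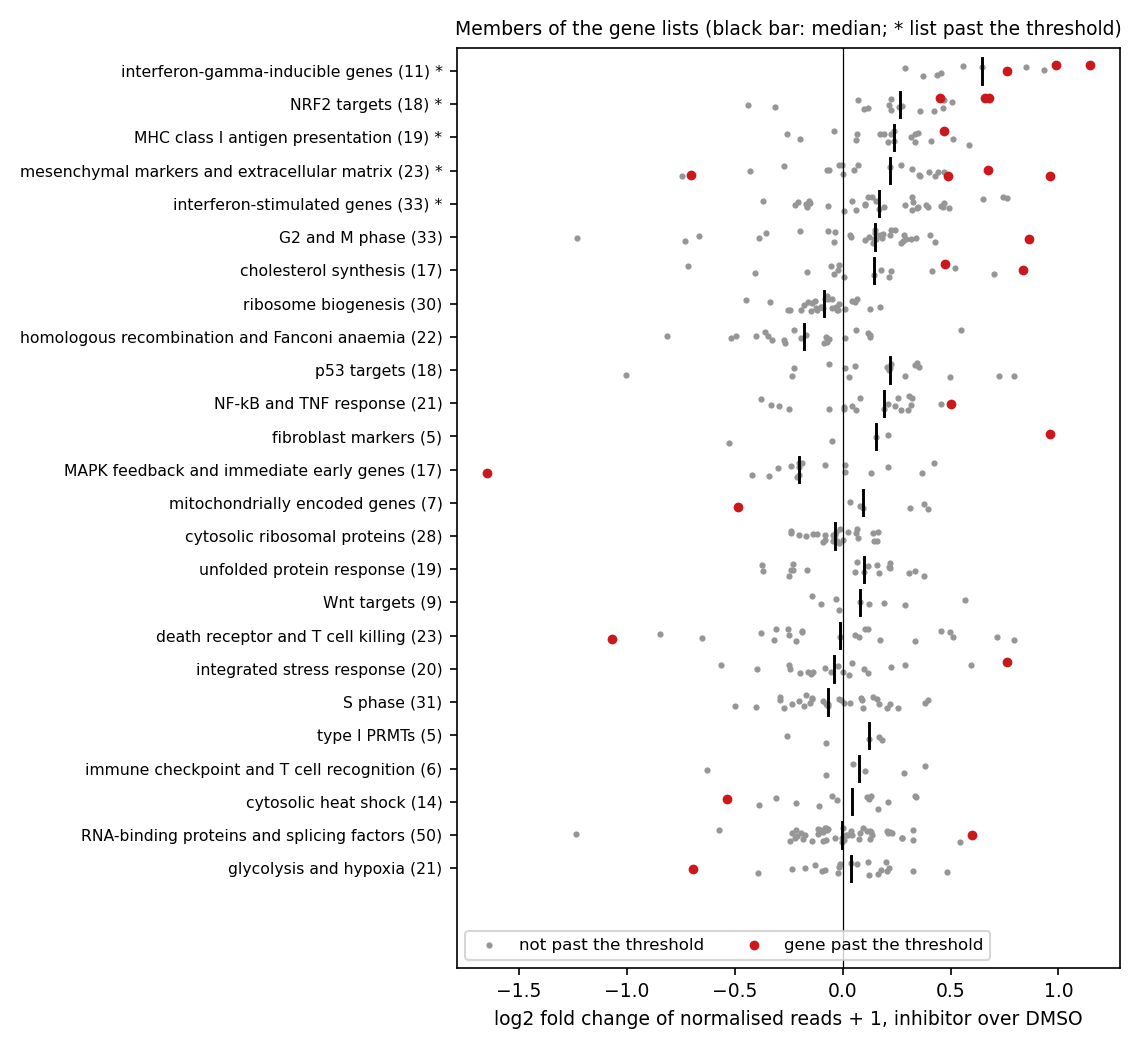
Log2 fold change of normalised reads plus 1, inhibitor over DMSO (x axis), of each tested member of the 25 lists tested, in order of the list's camera p-value, with the number tested in brackets. Red points are genes past the threshold and black bars medians. The 11 tested interferon-gamma-inducible genes all lie above 0, with a median of 0.65.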

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

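The tests on recovered reads, with the column letter as a block, and on genes with no opposite-strand exon were chosen after the data were seen. Against 111 genes higher and 72 lower, the counts were 12 and 4 with no abundance filter, and the cause was not tested. They were 59 and 37 at an adjusted p under 0.01 and 1 and 1 (Fam69a and Tuba1c) when a fold of 1.5 was tested on the deposited scale, both stricter by construction. The authors' deposited table gave 16 and 10, with fewer genes adjusted and another model. Leaving out each library gave 42 to 178 higher and 21 to 76 lower, with the lone library of the reduced group assumed to vary like the other group. DMSO A is the library without which the count lower exceeds the count higher. Only genes with no opposite-strand exon gave 62 and 47 among 5316 tested, 89 of these 109 being calls of the main test. Voom on recovered reads called 112 and 68 with the authors' size factors, 175 of them shared with the main calls. With library size only it called 67 and 58, which shifts the median log2 fold change by -0.04, and the cause of the lower count was not tested. Other scalings, pseudocounts and a mean CPM of at least 1 stayed within 1.5 times of the main counts.

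Both other ways of splitting the 4 libraries into 2 and 2 gave 0 genes in limma, with 249 and 174 genes at an unadjusted p under 0.05 against 1045 for inhibitor against DMSO. These splits are too few to give a share under 0.05. Both mixed inhibitor and DMSO libraries within each of their groups, with no term for treatment. Any change with the inhibitor thus entered their residual spread, which favours few calls, so the splits do not serve as a control for the 183 calls. The columns share letters across groups and nothing ties a letter to a shared day. A replicate block by column letter called 133 higher and 94 lower, all 183 calls of the fit without the block among them, and 129 and 81 in voom. The deviations of same-letter libraries correlated at 0.166 over 2041 genes. Of 38 called genes named by the rule, 17 were called without each library in turn. Of these 38, 27 were not called with no abundance filter, 9 not at an adjusted p under 0.01, 3 not without DMSO A, 8 without DMSO B, 14 without inhibitor A and 21 without inhibitor B. When a fold of 1.5 was tested, 36 were not called. With voom and library size only 7 were not (Tapbp, Cxcl1, Casp8, Aurka, Cryab, Fdft1, Txnrd1). Single calls were lost at a mean CPM of at least 1 (limma, adjusted p = 0.054 for Fdft1 and 0.060 for Txnrd1), with a pseudocount of 0.1 (Txnrd1, 0.051) and in voom with the authors' size factors (Casp8, 0.051), and 16 of the 36 with an adjusted p in the authors' deposited table were not called there. No called gene named by the rule and no called list changed sign. Among named genes that were not called, 6 did without 1 library or another (B2m, Pmel, Prmt2, Prmt3, Prmt6, Prmt9).

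Of 5 lists called higher, 0 were called with an estimated correlation or with fry's test of direction (adjusted p from 0.11 to 0.17), and 3 to 5 with each library left out. Fry's test for change in either direction passed for 10 lists (adjusted p under 0.05), which include the RNA-binding, integrated stress, glycolysis, cholesterol, NF-kB and fibroblast lists that camera did not call. Lists called lower went from 0 to between 0 and 1. All 5 were called when restricted to genes with no opposite-strand exon. At these counts and with 2 libraries per group, a 1.5-fold change was called in 56% of simulated cases, with a simulated spread below that of the real DMSO libraries. A quasi-likelihood count test, its TMM and size-factor scalings, a count-model fit with DESeq2 and a block by the labels' replicate numbers were not run. The count tests were planned for deposited counts, and reads recovered from base means were tested with voom instead. The columns carry no replicate number.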

Other observations

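The test of opposite-strand pairs and that of the median log2 fold change were set before their results were seen, and the other tests of this part after.

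Among 63 pairs of a called gene and a tested opposite-strand partner, the signs were the same in 38 and opposite in 25, and both members were called in 3 pairs, each in the same direction. Mns1, a cilium protein gene, rose by 0.91 ± 0.16 on the log2 scale (limma, adjusted p = 2.4e-05) and its opposite-strand neighbour Tex9 by 1.08 ± 0.15. The lysosomal protease gene Ctsb rose by 0.51 ± 0.15 (limma, adjusted p = 0.033) and its neighbour Fdft1 by 0.47 ± 0.14. Chpf2, of chondroitin sulfate synthesis, rose by 0.51 ± 0.14 (limma, adjusted p = 0.016) and Smarcd3, of the SWI/SNF chromatin remodeller, by 0.72 ± 0.15 (limma, adjusted p = 0.00081). Pairs that went apart include Tmem79 (1.06) with Glmp (-0.70) and Gas2l1 (0.74) with Rasl10a (-0.97), in which only the first member of each passed. Gm17334, which lies opposite Irf1 (0.45 ± 0.16, not past the threshold), rose from 808 ± 120 to 1177 ± 8.77 normalised reads (log2 fold change 0.55 ± 0.13; limma, adjusted p = 0.0061). Il12rb2, an interleukin 12 receptor chain (opposite Serbp1), rose by 1.35 ± 0.21 (limma, adjusted p = 6.9e-07), while Serbp1 had a log2 fold change of -0.29 ± 0.13.

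The most abundant values sat at genes opposite abundant genes, in libraries from a stranded kit. Counting without regard to strand is argued against: mt-Co1 would then exceed mt-Nd6, but the ratio of their reads was 0.0858. The reverse ratio, 11.7, is what counting on the strand opposite to the transcript would give, and that remains a candidate explanation. Plus-strand mt-Nd5, which shares 14 bp with mt-Nd6, was nonetheless given 6588 reads over the 4 libraries, against 9215 for mt-Nd6 and 791 for mt-Co1. The ratio to mt-Co1 alone thus does not settle the explanation. In ribosomal protein loci the opposite-strand partner held more reads for 3 of 6 genes (50%, exact 95% interval 11.8% to 88.2%), which decides nothing. If the explanation holds, reads at genes with no opposite-strand exon may be the leftover fraction of a stranded library, and no biological explanation such as antisense transcription was tested.

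Of 183 called genes, 94 (51.4%) had an opposite-strand exon, against 37.9% of tested genes. Random sets matched on base mean held 80 (95% of sets between 67 and 93, 10000 sets). Over 453 opposite-strand pairs with base means of at least 50, the log2 fold changes of the 2 members correlated across genes at a Spearman rho of 0.158 (10000 re-pairings gave -0.0902 to 0.0916). This is consistent with part of the calls at overlapping genes reporting a change of the partner's transcripts. Shared promoters or true coregulation of neighbours were not tested and stay open, and genes are not independent replicates.

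The 2 DMSO libraries differed more than the 2 inhibitor libraries (chi-square per gene 2.21 against 1.47). The median log2 ratio of DMSO A to DMSO B was -0.17 at genes with an opposite-strand exon and 0.03 at genes without, a difference of -0.208 (95% bootstrap interval -0.23 to -0.19, 2039 genes with a base mean of at least 100). Between the inhibitor libraries the difference was -0.01. A difference between the DMSO libraries in the share of reads on the unintended strand may thus account for part of their spread, and a difference between cultures was not tested. Between the groups, the median log2 fold change of genes without an opposite-strand exon differed from that of genes with one by -0.014 (95% bootstrap interval -0.030 to -9.6e-05). This lies inside the limit of 0.1 set beforehand and argues against such a shift in the averages of these 4 libraries over all tested genes. The bootstrap intervals resample genes and leave out the spread between libraries, so the result does not extend beyond these libraries. The difference cannot tell why more genes rose than fell, as a median over all tested genes need not follow the called ones. The counts were 68 higher and 76 lower without DMSO A and 178 and 55 without DMSO B, and why they depend on the DMSO library was not tested.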
